A study of Homo sapiens with 27 samples.

How the data were processed

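Gene expression was measured by RNA sequencing in 27 libraries of A375 cells, an established line grown from a human melanoma with an activating mutation of the kinase BRAF. Per the labels, the cells were cultured in DMEM with 10% FBS, treated for 24 h, lysed for total RNA with the QIAGEN RNeasy Plus Mini kit, and turned into polyA libraries with the KAPA stranded mRNA kit. Per the submitters' processing notes, which give names without order or version, bcl2fastq, HISAT2 and HTSeq were used with the hg38 build. The authors deposited 1 table of read counts per gene, as raw whole-number counts that were not normalized. The annotation release, the strand setting of the counting and the versions are not given in the sources used here. All 58721 gene identifiers of the table were found in GENCODE release 29, which was used for gene types and for coordinates on hg38, and current gene symbols were taken from a table of gene names. The table had 0 rows that name no gene, such as a total of unassigned reads. It had 45 rows for Y copies of pseudoautosomal genes, which were kept as deposited, and 12466 rows without a count in any library.

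From these counts, library totals, CPM (counts divided by the library total times its TMM factor, from edgeR's cpm) and all tests were computed. Groups came from the sample titles and the genotype and treatment labels, and each of the 9 groups had 3 libraries. Within a group, every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom between 3.05 and 13.2 and a Pearson r across genes of at least 0.99119, so no library was counted as a copy of another. Genes with low counts were removed with filterByExpr, which left 25199 genes. The main test was edgeR's quasi-likelihood test with TMM normalization and robust dispersion on all 27 libraries, fitted as 9 group means with 18 residual degrees of freedom. A gene was called when its p, adjusted by the Benjamini-Hochberg method over all genes tested, was under 0.05. Adjusted p-values of single genes in the text come from that test. The knockout effect was the mean of both guides minus the control guide, and the interaction was the drug response of knockout cells minus that of control cells. Differences between the guides were coded as guide 2 minus guide 1. An error after a log2 fold change is its standard error, and an error after a CPM value is the SD of 3 libraries. TMM factors lay between 0.866 and 1.09. Fold changes are relative to the bulk of genes in each library, so a change in total RNA per cell would not show.

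The text names, for each comparison, the 6 largest rises and the 6 largest falls at most, taken among called protein-coding genes that average at least 1 log2-CPM, carry a symbol and have every library of either side apart from the other side. In knockout comparisons these genes also had to be called with each guide in the same direction, and in interactions no separation of libraries was asked. It also names 2 to 4 of the called members with the largest change from each list it describes, and in any comparison TADA2B, DUSP6, SPRY4, CCND1, MITF, MLANA, SOX10, NGFR, AXL and EGFR. A few genes that this rule picks are left out of the text. The lists described are those past the threshold of the set test in that comparison, plus MAPK output, melanocyte differentiation, neural crest-like, undifferentiated melanoma, the SAGA complex and the cell cycle lists. Where a comparison had many such lists, those with the weakest effects are given by count or median alone.

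A total of 33 gene lists was written from general knowledge. They cover MAPK output, melanocyte differentiation, neural crest-like and undifferentiated melanoma states, the SAGA and ATAC complexes, G2/M and mitosis, S phase and DNA replication, interferon response, MHC class I and class II antigen presentation, cholesterol synthesis, glycolysis, oxidative phosphorylation, lysosome, p53 targets, the BCL2 family, receptor tyrosine kinases and ligands, extracellular matrix, YAP/TEAD targets, TGF-beta targets, MYC targets and ribosome biogenesis, the AP-1 family, ATF4 and unfolded protein response, hypoxia response, inflammatory cytokines and NF-kB, heat shock, keratinocyte, fibroblast, leukocyte and endothelial markers, mitochondrially encoded genes and replication-dependent histones. The matching found 40 of 42 histone genes and every member of the other lists. Lists were tested against all other genes with camera on voom values, with the correlation between genes preset at 0.01 and the p adjusted over the 33 lists of a comparison. An estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were run beside it. The design, the main test, the lists, the rule for named genes and the alternative settings were fixed before the data were examined.

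The alternatives were DESeq2's size factors in place of TMM, DESeq2's Wald test, limma voom, no low-count filter, a filter of at least 1 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block, a further threshold of 2-fold, and leaving out each library in turn. Comparisons that share control libraries were set beside 20 simulations of unchanged groups against those controls. The code was tested on simulated counts in which 50 genes at each size of change were altered. For trametinib in control cells, with 24323 genes in the simulation, it recovered 42% of 1.25-fold, 56% of 1.5-fold, 68% of 2-fold and 86% of 4-fold changes, and 4 of 24091 unchanged genes were called. For the knockout in DMSO, with 24293 genes, it recovered 60%, 52%, 78% and 96% of the same sizes, and 5 of 24057 unchanged genes were called. For the interaction with trametinib, with 24305 genes, it recovered 48%, 54%, 68% and 82%, and 10 of 24069 unchanged genes were called. The interferon response list was also shifted 1.5-fold in each simulation. In turn 166, 187 and 171 genes were called, far fewer than in the real comparisons. These shares therefore test the code and do not give the power or error of the real comparisons. Principal components were computed on log2-CPM with a prior count of 2. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

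Library totals ran from 67502300 to 92513726 counts, with a median of 79524936. At these depths 3 counts, used as the floor for a gene without a count, equal 0.0444 CPM in the shallowest library and 0.0324 CPM in the deepest. The sources used here name no molecular identifiers, so floors cover counting error only. Counts of genes with a near-identical copy, such as C4A and C4B, HSPA1A and HSPA1B, HLA genes, keratins and histones, can be split or lost between the copies and are uncertain, and with the strand setting not given the same holds for overlapping genes. KIT had 0 counts in every library of control cells in DMSO, so no fold is given against that group.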

Results

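RNA was sequenced from 27 libraries of A375 cells, a human melanoma line with an activating BRAF mutation, in 9 groups of 3. The groups crossed 3 cell populations with 3 treatments of 24 h. The control population carried a guide RNA against GFP, which targets no human gene, and the other populations were TADA2B knockouts made with guide 1 or guide 2. TADA2B is a subunit of SAGA, a complex that acetylates histones and acts on transcription. The treatments were DMSO, the solvent, 20 nM trametinib, an inhibitor of the kinase MEK, and 1 µM vemurafenib, an inhibitor of mutant BRAF, which acts just upstream of MEK in the MAPK cascade. The study's title names plasticity of melanoma cell states and resistance to therapy, and the comparisons ask what each drug changed, what the knockout changed in each treatment, and whether the knockout altered the response to each drug. Library totals lay between 67502300 and 92513726 counts. On a principal component analysis, component 1, with 47.3% of the variance, set DMSO libraries apart from those given a drug, and component 2, with 24.1%, set control libraries apart from knockout libraries. Mitochondrially encoded genes took 1.616% ± 0.053 (SD, n = 3) of the counts in control cells in DMSO, 2.537% ± 0.205 with guide 1 and 2.598% ± 0.088 with guide 2, and between 2.195% and 3.497% on average in the groups given a drug. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. That spread was small, with a common biological coefficient of variation of 4.02%, and small changes passed the test, so counts of genes changed at least 2-fold are given beside all counts.

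**Figure D1:**
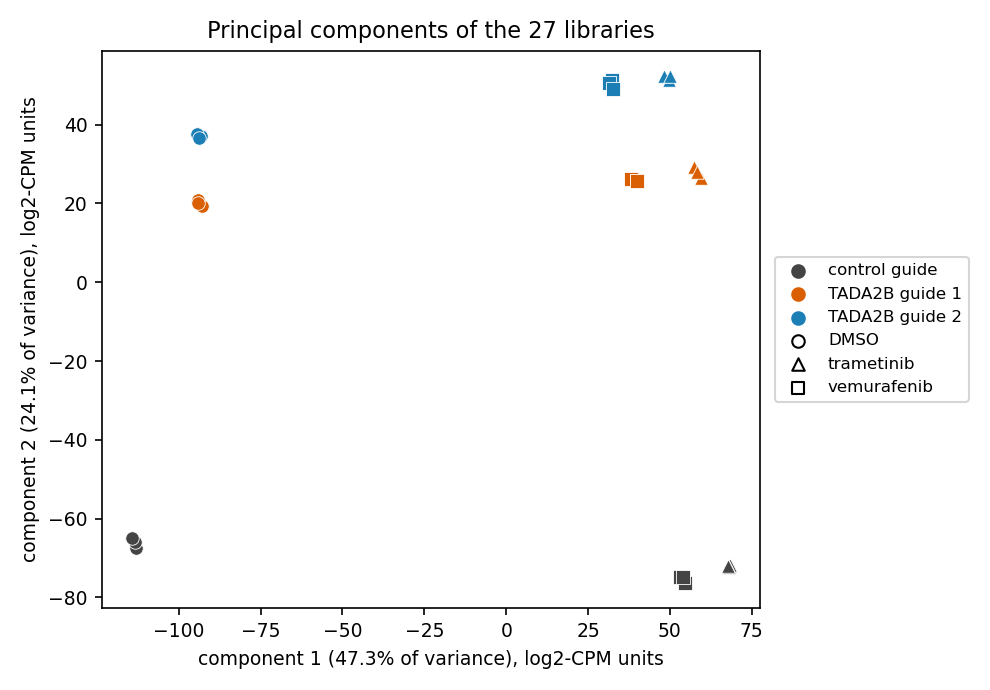
Principal components of log2-CPM, 1 point per library, coloured by cell population and shaped by treatment, with component 1 (47.3% of the variance) on the horizontal and component 2 (24.1%) on the vertical axis. DMSO libraries lie between -114.2 and -92.9 on component 1 and all libraries given a drug at 31.3 or above, while control libraries lie at -65 or below on component 2 and knockout libraries at 19.3 or above.

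TADA2B (ENSG00000173011, chromosome 4, 7041899 to 7057952, plus strand, hg38), the targeted gene, kept most of its transcript in the knockout populations. In DMSO TADA2B stood at 31.2 CPM ± 0.931 (SD, n = 3) in control cells, 30.4 ± 0.773 with guide 1 and 28.6 ± 1.21 with guide 2. The guide 1 level was 97.6% of control, a difference that did not pass the test (log2 -0.04 ± 0.043, adjusted p = 0.52), and the guide 2 level fell to 91.8% of control (log2 -0.12 ± 0.043, adjusted p = 0.013). That call was lost without replicate 3 of control cells in DMSO (log2 -0.102, adjusted p = 0.072) and without replicate 2 of guide 2 in DMSO (log2 -0.089, adjusted p = 0.12). Both drugs raised TADA2B in control cells, to 41.3 CPM ± 1.27 with trametinib (log2 0.41 ± 0.042) and 43.8 CPM ± 1.37 with vemurafenib (log2 0.49 ± 0.042). Against those levels, guide 1 cells held 84.5% of control in trametinib and 74.4% in vemurafenib, and guide 2 cells held 71% and 65.1%, each past the test. A gene edited by a guide can keep its transcript, so these levels neither check nor contradict the genotype labels.

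**Figure D2:**
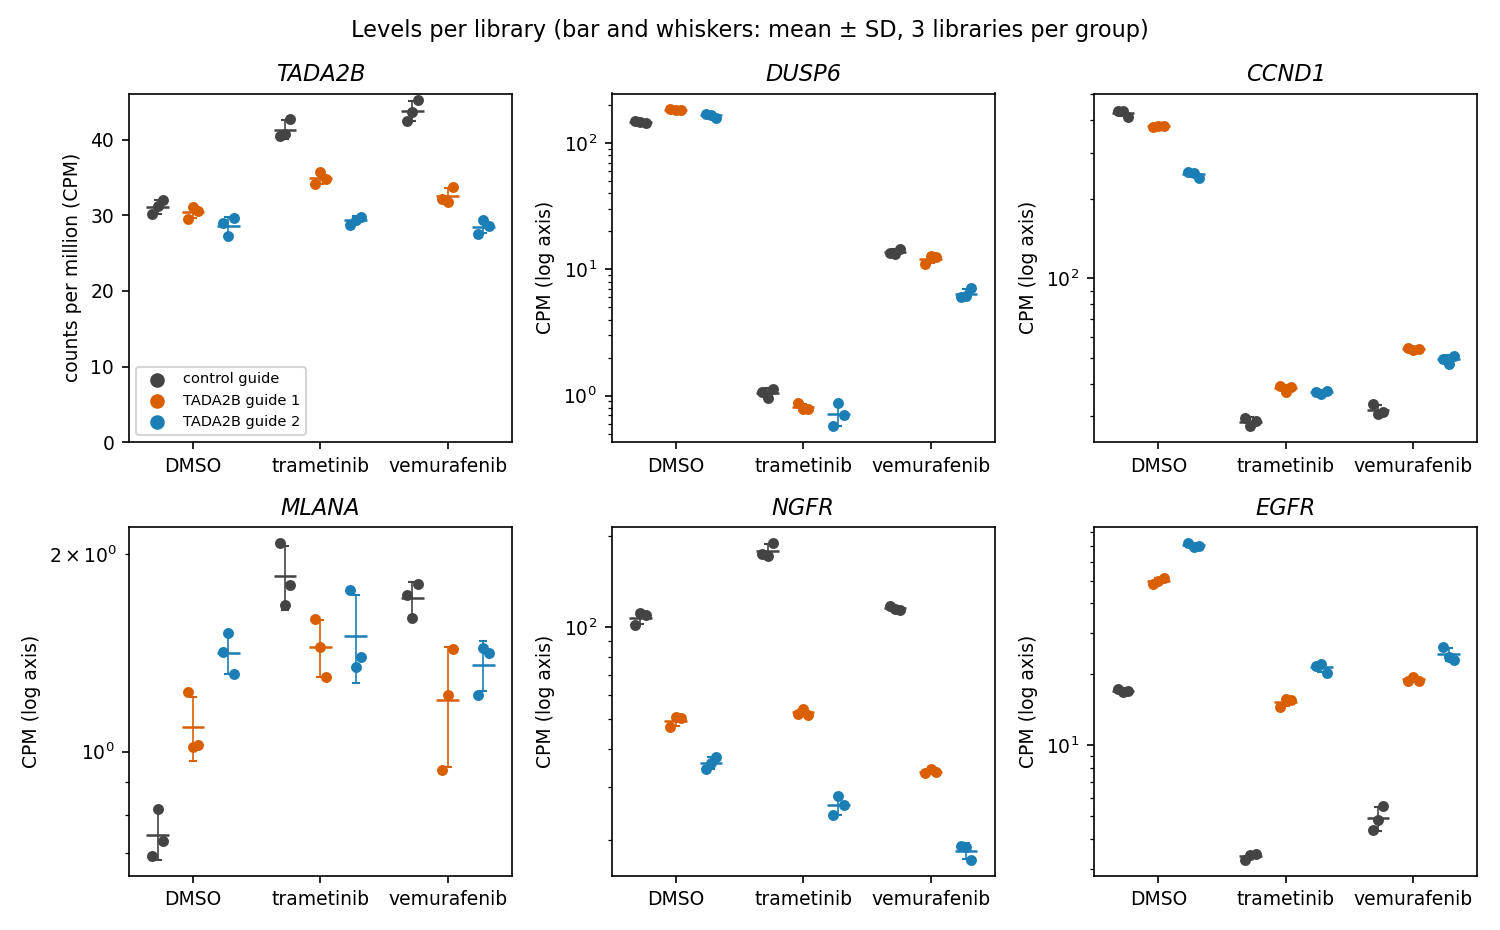
Levels of TADA2B (linear axis), DUSP6, CCND1, MLANA, NGFR and EGFR (log axes) in CPM, 1 point per library and group, with bars and whiskers for the mean ± SD of 3 libraries. DUSP6 lies at 147 CPM in control cells in DMSO and 1.05 CPM in trametinib, while EGFR lies at 17 CPM in control cells and 49.8 (guide 1) and 70.7 CPM (guide 2) in knockout cells in DMSO.

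Trametinib in control cells lowered genes that MAPK signalling drives and raised genes of melanocyte differentiation. SPRY4 (ENSG00000187678, chromosome 5, 142310427 to 142326455, minus strand), a feedback inhibitor of receptor signalling, fell 269-fold, from 443 CPM ± 3.31 to 1.64 ± 0.177 (log2 -8.07 ± 0.053, n = 3 per group). DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271, minus strand), a phosphatase that switches off ERK, fell 140-fold (log2 -7.12 ± 0.067), and ETV4 and ETV5, transcription factors induced by ERK, fell 128-fold and 83-fold. CEMIP, a protein that helps break down hyaluronan, fell 296-fold from 543 CPM, and LPL, which hydrolyses triglycerides, fell 108-fold. DCT (ENSG00000080166, chromosome 13, 94436808 to 94479682, minus strand), an enzyme of melanin synthesis, rose 1120-fold, from 0.938 CPM ± 0.161 to 1050 ± 14.5 (log2 10.12 ± 0.057). GRIN2A, a glutamate receptor subunit, rose 268-fold, and PCSK2, a protease that processes hormones, rose 123-fold. CD36, a fatty acid receptor, PRUNE2, and the collagen COL21A1 rose 113-fold, 95.3-fold and 80.1-fold. Among the remaining genes named in every comparison, cyclin D1 (CCND1), which drives entry into S phase, fell 14.8-fold, EGFR 5.01-fold and the receptor AXL 1.56-fold. MITF, the main transcription factor of melanocytes, rose 1.77-fold, its target MLANA 2.47-fold, the nerve growth factor receptor NGFR 1.66-fold and SOX10, a neural crest factor, 1.18-fold. MLANA was low throughout, from 0.69 to 0.82 CPM in control libraries in DMSO and at most 2.08 CPM in any library. Its fold changes in every comparison are therefore between low levels.

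By list, 24 of 25 MAPK output genes fell with trametinib and 1 rose (median log2 -3.34, camera adjusted p = 9.96e-18), with SPRY1 at log2 -7.38 ± 0.16. The cell cycle lists fell as a whole. All 30 genes of G2/M and mitosis were lower (median -3.08, adjusted p = 2.86e-26), among them UBE2C at -3.71 ± 0.054 and TTK at -3.54 ± 0.065. All 36 genes of S phase and DNA replication were lower too (median -2.37, adjusted p = 1.22e-24), led by MCM10 at -6.14 ± 0.1 and E2F2 at -5.61 ± 0.14. Of 40 MYC targets and ribosome biogenesis genes, 39 fell (median -1.25), MYC itself by 4.07 on the log2 scale, and 17 of 19 heat shock genes fell (median -1.25), HSPA8 by 2.36. Lower lists also included cholesterol synthesis (18 of 24 lower, median -0.69, DHCR7 -1.78 ± 0.042), YAP/TEAD targets (18 of 26, median -0.53, IGFBP3 -5.45 ± 0.089), and inflammatory cytokines and NF-kB (16 of 24, median -0.74). In the last list the chemokine CXCL8 fell by 7.61, and by 8.64 without replicate 3 of control cells in trametinib, which holds most of the few remaining counts. Of 23 melanocyte differentiation genes 16 rose and 5 fell (median 0.83, adjusted p = 0.0151), with CITED1 at 5.06 ± 0.14, and of 24 p53 targets 17 rose and 6 fell (median 0.41), with TP53INP1 at 2.70 ± 0.047 and the cell death gene PMAIP1 at -4.04 ± 0.11.

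Another 9 lists passed the set test for trametinib in control cells only with the preset correlation. Glycolysis was lower (20 of 22, median -0.79, adjusted p = 0.0749 with an estimated correlation), with LDHA at -1.84 ± 0.027. Undifferentiated melanoma genes were lower (20 of 28, median -0.85, adjusted p = 0.0969 with an estimated correlation). Lower too were oxidative phosphorylation (26 of 35, median -0.32, adjusted p = 0.4 with an estimated correlation) and ATF4 and unfolded protein response (20 of 30, median -0.57, adjusted p = 0.211 with an estimated correlation). Interferon response genes were higher (33 of 42, median 0.72, adjusted p = 0.294 with an estimated correlation). So were lysosome genes (33 of 40, median 0.51, adjusted p = 0.127 with an estimated correlation) and neural crest-like genes (15 of 22, median 0.66, adjusted p = 0.0684 with an estimated correlation), with SNAI2 at 3.33 ± 0.079. The AP-1 family, transcription factors built of FOS and JUN subunits, was higher (8 of 14, median 0.43, adjusted p = 0.157 with an estimated correlation), with JUN at 6.00 ± 0.046, ATF3 at 5.84 ± 0.063 and FOSL1 at -3.90 ± 0.052. MHC class I genes were higher (12 of 17, median 0.41, adjusted p = 0.455 with an estimated correlation). The SAGA complex list did not pass (11 higher and 9 lower of 25, median 0.08, adjusted p = 0.633), although KAT2B, an acetyltransferase subunit, rose by 2.24 ± 0.033.

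In all, 17376 of 25199 genes were called for trametinib in control cells, 9185 higher and 8191 lower, and 7454 of them changed at least 2-fold, 4317 upward and 3137 downward. Adjusted over the list alone, the counts differed for 5 lists, by 1 gene each: 16 higher for neural crest-like, 12 higher for SAGA, and 5, 27 and 24 lower for MHC class I, oxidative phosphorylation and receptor tyrosine kinases. Across the 10 comparisons, camera called 160 of 330 list results, and 80 of these held with an estimated correlation. Median, mean and test differed in sign for TGF-beta targets, keratinocyte markers, leukocyte markers and histones here, none of them called.

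**Figure D3:**
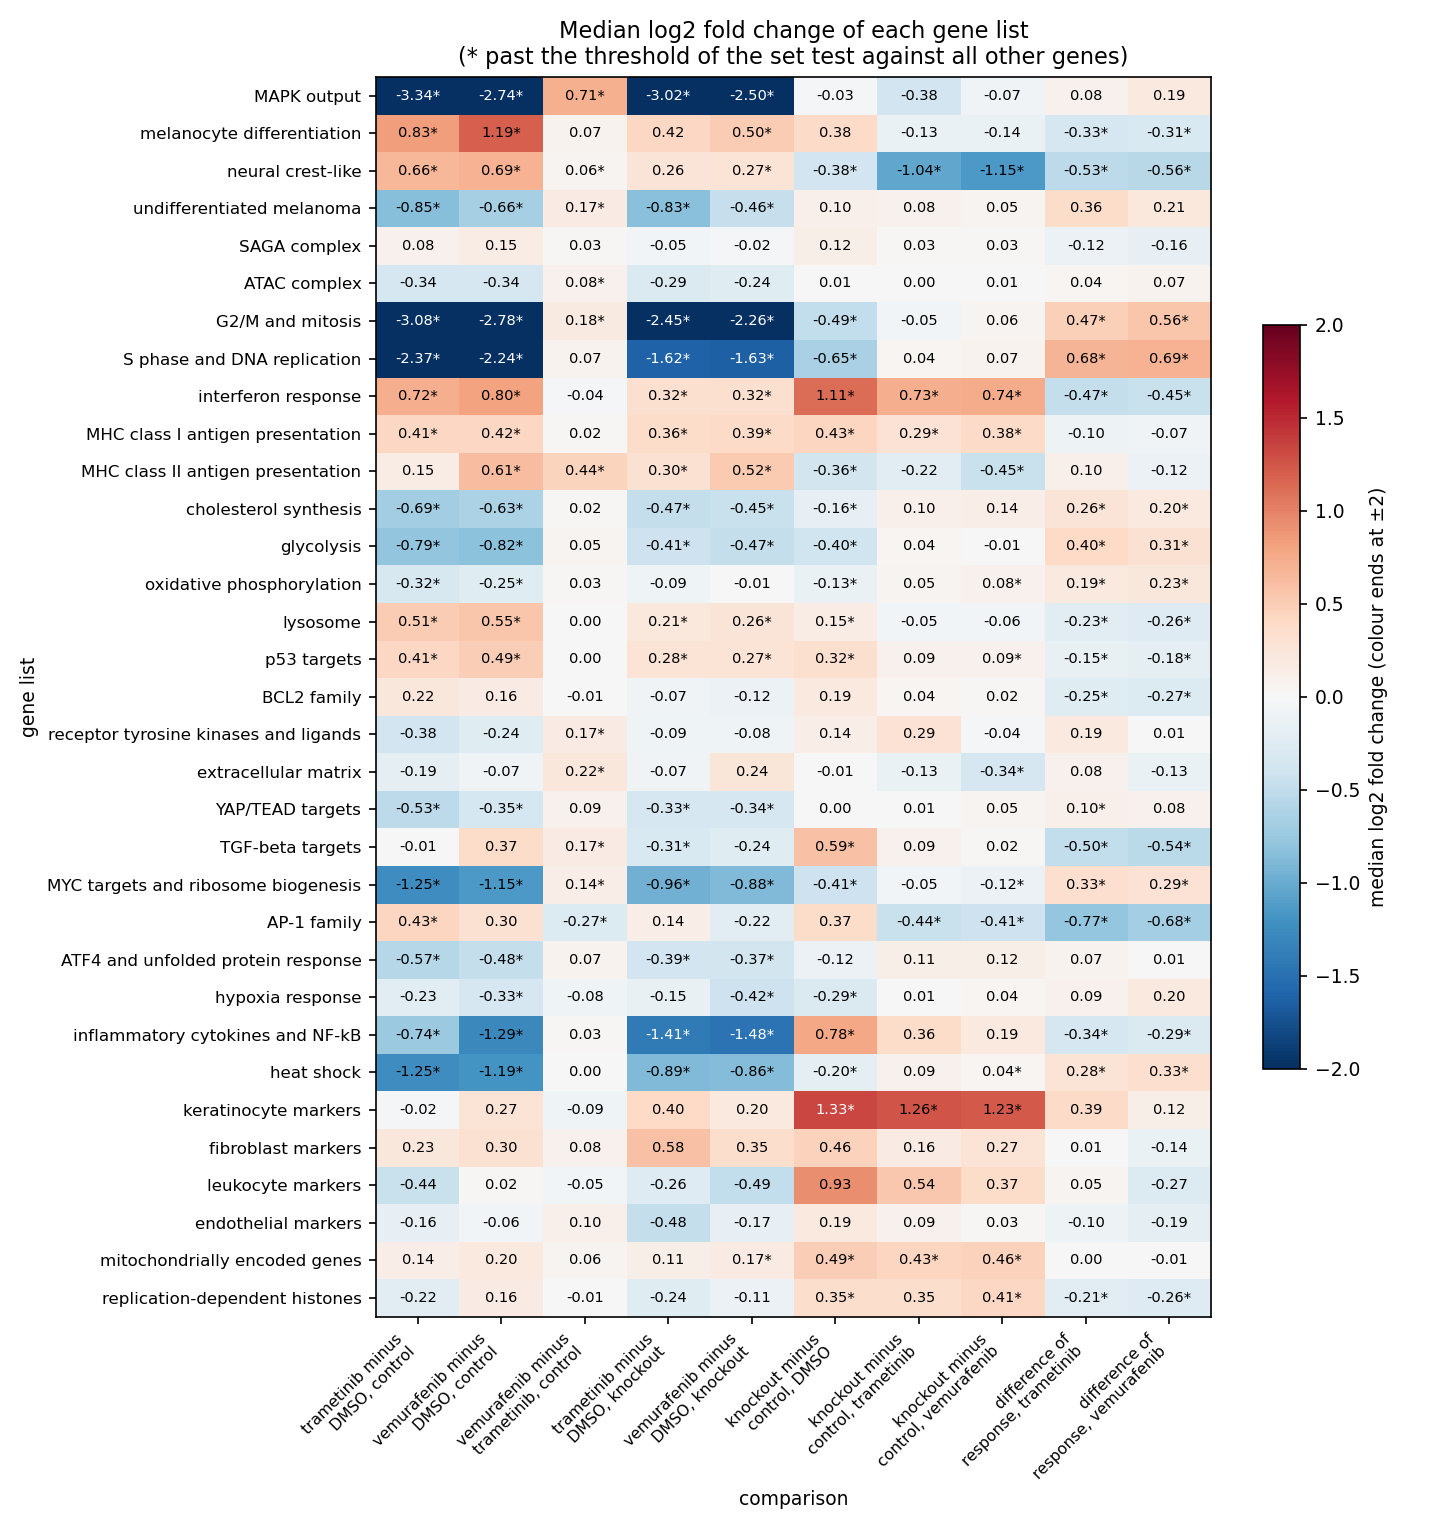
Median log2 fold change (colour, ends at ±2) of the 33 gene lists (vertical) in the 10 comparisons of drug, knockout and interaction (horizontal), with an asterisk where the set test against all other genes passed its threshold. G2/M and mitosis stands at -3.08 for trametinib in control cells, -0.49 for the knockout in DMSO and 0.47 for the interaction with trametinib.

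In control cells given vemurafenib, DCT rose 1050-fold to 985 CPM ± 12.1 (log2 10.04 ± 0.057), PCSK2 97.6-fold, COL21A1 76.8-fold, PRUNE2 66.1-fold, CD36 64.3-fold and CCN3, a matrix-associated signalling protein, 53.6-fold. CEMIP fell 195-fold, SPRY4 103-fold to 4.3 CPM ± 0.116, ETV4 65.1-fold, MCM10, a replication factor, 56.8-fold, LPL 54.8-fold and CXCL8 43.9-fold. DUSP6 fell 10.6-fold to 13.8 CPM ± 0.679, CCND1 13.4-fold, EGFR 3.47-fold and AXL 1.73-fold, while MITF rose 1.88-fold, MLANA 2.28-fold and SOX10 1.24-fold. NGFR was called at 1.08-fold (adjusted p = 0.027), a call lost without replicate 1 of control cells in DMSO (log2 0.06). Of the lists, MAPK output (24 of 25 lower, median -2.74, SPRY1 -5.24 ± 0.13) and G2/M and mitosis (30 of 30 lower, median -2.78, AURKB -3.36 ± 0.056) fell. S phase and DNA replication (36 of 36 lower, median -2.24, E2F1 -4.34 ± 0.08), MYC targets (39 of 40 lower, median -1.15, LYAR -2.36 ± 0.047) and heat shock (17 of 19 lower, median -1.19, HSPA8 -2.30 ± 0.033) fell. Inflammatory cytokines and NF-kB (17 of 24 lower, median -1.29, CXCL1 -2.93 ± 0.16) and cholesterol synthesis (18 of 24 lower, median -0.63, DHCR7 -1.61 ± 0.042) fell as well. YAP/TEAD targets (19 of 26 lower, median -0.35, IGFBP3 -4.97 ± 0.084) and hypoxia response (13 of 24 lower, median -0.33, with the carbonic anhydrase CA9 at -3.88 ± 0.2) were lower too. Melanocyte differentiation (16 of 23 higher, median 1.19), neural crest-like genes (17 of 22 higher, median 0.69, SOX2 2.67 ± 0.062) and p53 targets (17 of 24 higher, median 0.49, TP53INP1 2.37 ± 0.047) rose. These 12 lists held with an estimated correlation. The other 8 called lists did not, among them MHC class II antigen presentation (13 of 14 higher, median 0.61, adjusted p = 0.0662 with an estimated correlation), with the protease CTSS at 1.90 ± 0.094. Glycolysis was another (20 of 22 lower, median -0.82, adjusted p = 0.0537 with an estimated correlation). Interferon response genes were higher (32 of 42 higher, median 0.80, adjusted p = 0.28 with an estimated correlation) and undifferentiated melanoma genes lower (17 of 28, median -0.66, adjusted p = 0.21 with an estimated correlation). MHC class I and lysosome genes were higher (medians 0.42 and 0.55, adjusted p = 0.372 and 0.113 with an estimated correlation), and oxidative phosphorylation and the ATF4 list lower (medians -0.25 and -0.48, adjusted p = 0.447 and 0.196 with an estimated correlation). SAGA genes did not pass (14 higher and 9 lower of 25, adjusted p = 0.469), with KAT2B at 2.88 ± 0.034. In all 16957 genes were called, 8993 higher and 7964 lower, of which 6920 changed at least 2-fold (4060 upward, 2860 downward). Adjusted over the list alone, the melanocyte list had 17 higher, receptor tyrosine kinases 14 higher and keratinocyte markers 8 higher in place of 16, 13 and 7, and other counts were equal. Signs of median, mean and test differed for 5 lists, none called: extracellular matrix, histones, and keratinocyte, leukocyte and endothelial markers.

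Across all 25199 genes, the responses to the drugs had a Pearson r of 0.94, and 15525 genes were called in both with the same sign (8196 higher, 7329 lower) against 82 with opposite signs. Independent lists of these sizes would share 3278 higher and 2589 lower genes. Both responses use the same DMSO libraries: in 20 simulations of unchanged groups against these controls the median r was 0.508, no gene was shared, and the covariance was 0.0264 against 1.82 observed. With no gene changed, few calls can arise, so the lack of shared genes there does not show what shared controls add. The 3 controls are too few to split, so part of the excess over independent lists may come from the shared controls, and genes are not independent replicates.

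Set against each other in control cells, vemurafenib left more MAPK-driven RNA than trametinib. DUSP6 was 13.2-fold higher (log2 3.72 ± 0.081), SPRY2, a feedback inhibitor, 4.63-fold, and SPRY4 2.61-fold, and 21 of 25 MAPK output genes were higher and 3 lower (median 0.71, adjusted p = 2.68e-23). TFAP2B, a neural crest transcription factor, was 5.06-fold higher, SH3TC2 6.67-fold, PLEKHS1 3.78-fold and the sulfate transporter SLC26A2 3.4-fold. LRRC15 was 5.71-fold lower, the autophagy gene MAP1LC3C 5.48-fold, the growth factor FGF5 3.3-fold, the cytokine IL1A 3.09-fold and CRYGS, a crystallin, 2.82-fold. GOLGA8S (3.38-fold lower) belongs to a family of near-identical copies and is uncertain. EGFR was 1.45-fold higher, NGFR 1.54-fold lower and AXL 1.11-fold lower. CCND1 was 1.11-fold higher (adjusted p = 0.003), a call lost without replicate 1 of control cells in vemurafenib (log2 0.11). TADA2B, MITF, MLANA and SOX10 differed by 1.08-fold or less and did not pass (adjusted p from 0.068 to 0.73). Lists higher in vemurafenib, also with an estimated correlation, were MHC class II antigen presentation (12 of 14, median 0.44, with its activator CIITA at 0.93 ± 0.036) and extracellular matrix (20 of 39, median 0.22, THBS1 1.24 ± 0.029). The same held for MYC targets (29 of 40, median 0.14, MYC 1.33 ± 0.12), undifferentiated melanoma (16 of 28, median 0.17) and TGF-beta targets (12 of 24, median 0.17, ITGB3 1.28 ± 0.054). The AP-1 family was lower (7 of 14, median -0.27, adjusted p = 2.7e-10), with ATF3 at -1.35 ± 0.044 and FOS at -1.28 ± 0.056. G2/M genes (15 of 30 higher, median 0.18, adjusted p = 0.114 with an estimated correlation) and neural crest-like genes (8 of 22 higher, median 0.06, adjusted p = 0.0578 with an estimated correlation) were called with the preset correlation alone. So were the ATAC complex (3 of 15 higher, median 0.08, adjusted p = 0.0673 with an estimated correlation) and receptor tyrosine kinases and ligands (15 of 40 higher, median 0.17, adjusted p = 0.19 with an estimated correlation). S phase genes (median 0.07, adjusted p = 0.21), melanocyte differentiation (median 0.07, adjusted p = 0.358) and SAGA (median 0.03, adjusted p = 0.124) did not pass. The comparison called 4117 genes, 2212 higher and 1905 lower, but 362 changed at least 2-fold (191 upward, 171 downward). Adjusted over the list alone, 32 MYC targets, 18 G2/M genes, 22 matrix genes and 6 ATAC genes were higher. Signs of median, mean and test differed for 7 uncalled lists, such as interferon response and fibroblast markers.

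In DMSO, TADA2B knockout cells differed from control cells in interferon response genes, keratinocyte markers and neural crest-like genes, among other lists. PLAU (ENSG00000122861, chromosome 10, 73909177 to 73917497, plus strand), the urokinase plasminogen activator, rose 50.8-fold, from 0.147 CPM ± 0.052 to 5.57 ± 0.359 with guide 1 and 10.1 ± 0.938 with guide 2 (log2 5.67 ± 0.19). TNFRSF9, a receptor of the TNF family, rose 27.9-fold, COL17A1, a collagen of hemidesmosomes, 22.3-fold, the G protein regulator RGS4 18.7-fold and DIO2, which activates thyroid hormone, 16.5-fold. FAT3 (ENSG00000165323, chromosome 11, 92352096 to 92896470, plus strand), a large cadherin, fell 14.4-fold, from 21.7 CPM ± 0.0699 to 1.65 ± 0.121 and 1.37 ± 0.138. SLC24A2, an ion exchanger, fell 7.59-fold, HAPLN1, which links hyaluronan to proteoglycans, 6.93-fold, the integrin ITGA9 6.67-fold, the transcription factor SOX11 6.53-fold and ITIH5 6.29-fold. SOX10 fell 2.49-fold (log2 -1.32 ± 0.031) and NGFR 2.55-fold (log2 -1.35 ± 0.037), while EGFR rose 3.49-fold (log2 1.80 ± 0.047). SPRY4 fell 2.91-fold, AXL 1.49-fold, MITF 1.4-fold and CCND1 1.39-fold, and DUSP6 rose 1.19-fold and MLANA 1.66-fold. TADA2B itself missed the threshold for the mean of both guides (adjusted p = 0.063), and passed it when some single libraries were left out (log2 -0.1 without replicate 1 of control cells in DMSO).

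Of 42 interferon response genes 39 rose and 1 fell in the knockout in DMSO (median 1.11, adjusted p = 5.55e-19), among them RSAD2, an antiviral enzyme, at log2 5.74 ± 0.42 and OASL at 3.62 ± 0.14. RSAD2 stood at 0.092 CPM ± 0.02 in control cells and 4.95 ± 0.999 and 4.99 ± 1.39 with the guides. Inflammatory cytokines and NF-kB rose (19 of 24, median 0.78, IL1B 2.97 ± 0.18, CCL2 2.75 ± 0.11). So did TGF-beta targets (18 of 24, median 0.59, with LTBP2 at 1.98 ± 0.066) and p53 targets (19 of 24, median 0.32, FAS 1.33 ± 0.045, CDKN1A 0.95 ± 0.03). Keratinocyte markers rose (16 of 19, median 1.33, adjusted p = 3.82e-06), with the cell cycle inhibitor SFN at 3.15 ± 0.088 and the keratin KRT15 at 2.61 ± 0.068. All 36 S phase genes (median -0.65, adjusted p = 2.14e-23, MCM10 -0.95 ± 0.056) and 29 of 30 G2/M genes (median -0.49, CDK1 -0.87 ± 0.037) fell. MYC targets (37 of 40 lower, median -0.41, MYC -1.22 ± 0.074) and glycolysis (20 of 22 lower, median -0.40, HK2 -1.26 ± 0.027) fell too. Hypoxia response (14 of 24 lower, median -0.29, CA9 -2.08 ± 0.13, but the hormone STC1 at 3.22 ± 0.04) and neural crest-like genes (15 of 22 lower, median -0.38, RXRG -2.35 ± 0.061, but SOX9 at 2.72 ± 0.15) were also lower. These 11 lists held with an estimated correlation.

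The 8 calls for the knockout in DMSO that were lost with an estimated correlation were spread over housekeeping and antigen presentation lists. All 13 mitochondrially encoded genes rose (median 0.49, adjusted p = 0.176 with an estimated correlation), MT-ND1 by 0.96 ± 0.06. MHC class I genes were higher (15 of 17, median 0.43, adjusted p = 0.116 with an estimated correlation), with their activator NLRC5 at 1.04 ± 0.045. MHC class II genes were lower (10 of 14, median -0.36, adjusted p = 0.22 with an estimated correlation), with CD74 at -0.63 ± 0.029 but CTSS at 2.40 ± 0.084. The guides differed here, with medians of -0.03 for guide 1 and -0.71 for guide 2, and 7 genes were lower with each. Lysosome genes were higher (27 of 40, median 0.15, adjusted p = 0.22 with an estimated correlation), and so were 13 of 36 histone genes (median 0.35, adjusted p = 0.22 with an estimated correlation). The libraries were made from polyA RNA, so histone levels here cover only transcripts with a polyA tail and do not measure histone RNA as a whole. The levels were low, with a mean log2-CPM of -0.88 in control cells and -0.39 and -0.19 with guide 1 and guide 2. In the histone list replicate 1 of control cells in DMSO stood apart, with a mean log2-CPM of -1.5 against -0.57 and -0.59 in the other replicates. Cholesterol synthesis (16 of 24 lower, median -0.16, adjusted p = 0.116 with an estimated correlation), oxidative phosphorylation (20 of 35 lower, median -0.13, adjusted p = 0.436 with an estimated correlation) and heat shock (10 of 19 lower, median -0.20, adjusted p = 0.401 with an estimated correlation) were lower. MAPK output did not pass (10 higher and 11 lower of 25, median -0.03, adjusted p = 0.372). Neither did undifferentiated melanoma (14 higher and 12 lower of 28, median 0.10, adjusted p = 0.756), melanocyte differentiation (9 higher and 8 lower of 23, adjusted p = 0.988) or SAGA (13 higher and 5 lower of 25, median 0.12, adjusted p = 0.223). The mean log2-CPM of the undifferentiated melanoma list rose more than its median, from 5.99 in control cells to 6.42 with guide 1 and 6.45 with guide 2. In the melanocyte list DCT was at -2.07 ± 0.15 and PPARGC1A at 2.70 ± 0.11, and the median and mean lay above 0 while the test pointed down. Fibroblast markers (7 higher and 2 lower of 17, adjusted p = 0.05), leukocyte markers (8 higher and 2 lower of 14, adjusted p = 0.0672) and endothelial markers (6 higher and 1 lower of 12, adjusted p = 0.498) did not pass either.

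The knockout in DMSO called 14593 genes, 7380 higher and 7213 lower, and 3178 of them changed at least 2-fold, 2279 upward and 899 downward. Each guide gave the same direction for 11438 genes (5890 higher, 5548 lower), 2268 of them at least 2-fold with both, and 62 genes went opposite ways. The effects of the guides had r = 0.887 across genes and a covariance of 0.814, against a median r of 0.502 and covariance of 0.0259 in 20 simulations of unchanged guides, and independent lists would share 1903 higher and 1697 lower genes. The guides share 3 control libraries, which are too few to split, so part of the excess may come from them. The control and knockout populations also differ in any history of their making, which the design does not separate from the loss of TADA2B. Adjusted over the list alone, the melanocyte list had 11 higher in place of 9, p53 targets 20 in place of 19 and the AP-1 family 10 in place of 9. Heat shock had 5 higher in place of 4, receptor tyrosine kinases 20 in place of 19, and SAGA 6 lower in place of 5. Signs of median, mean and test also differed for the ATAC complex, extracellular matrix and YAP/TEAD targets, none of them called.

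Under the drugs, knockout cells held less DCT and less RNA of neural crest-like genes than control cells and more of COL17A1 and of keratinocyte markers. In trametinib DCT was 12.5-fold lower, at 103 CPM ± 4.02 with guide 1 and 68 ± 0.227 with guide 2 against 1050 ± 14.5 (log2 -3.64 ± 0.027), and in vemurafenib it was 12.2-fold lower. PCSK2 was 10.7-fold lower in trametinib and 10.8-fold in vemurafenib, and CD36 8.96-fold and 8.45-fold. The synaptic vesicle gene SV2C (log2 -3.35), WIPF3 (9.91-fold) and the cytokine IL24 (8.96-fold) were lower in trametinib, and WIPF3, SV2C and the neuropeptide UCN2 9.62-fold, 8.69-fold and 8.01-fold lower in vemurafenib. COL17A1 was 48.4-fold higher in trametinib and 31.7-fold in vemurafenib, MMP12, a macrophage elastase, 19.9-fold and 18.7-fold, MAP2, which binds microtubules, 19.7-fold and 24.4-fold, and ANKRD1, a target of YAP, 17.3-fold and 18.7-fold. SHOC1 (41.1-fold) and DIO2 (20.7-fold) were among the largest rises in trametinib, and ELFN2 (29.7-fold) in vemurafenib. NGFR was 4.82-fold and 4.65-fold lower, SOX10 2.76-fold and 2.8-fold, MITF 1.57-fold and 1.62-fold, and DUSP6 1.38-fold and 1.57-fold, in trametinib and in vemurafenib. EGFR was 5.33-fold and 4.39-fold higher, CCND1 1.32-fold and 1.63-fold, and AXL 1.17-fold and 1.14-fold lower. SPRY4 in trametinib was 1.77-fold lower (log2 -0.82 ± 0.091), and MLANA in vemurafenib 1.34-fold (log2 -0.42 ± 0.14, adjusted p = 0.0073). MLANA in trametinib (log2 -0.33 ± 0.13, adjusted p = 0.031) was lost without replicate 1 of control cells (log2 -0.24), and SPRY4 in vemurafenib (log2 -0.16 ± 0.057, adjusted p = 0.013) without replicate 1 of guide 2 (log2 -0.14).

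Neural crest-like genes fell in the knockout under both drugs, 17 of 22 in trametinib (median -1.04, adjusted p = 2.69e-09, RXRG -2.29 ± 0.078) and 18 of 22 in vemurafenib (median -1.15, adjusted p = 1.06e-12, ERBB3 -1.80 ± 0.023). Keratinocyte markers rose, 16 of 19 under each drug (medians 1.26 and 1.23, SFN 3.84 ± 0.095 and 4.00 ± 0.11). Only these lists held with an estimated correlation in these comparisons. Interferon response genes were higher in trametinib (39 of 42, median 0.73, adjusted p = 0.114 with an estimated correlation), with BST2 at 2.40 ± 0.085, and in vemurafenib (37 of 42, median 0.74, adjusted p = 0.126 with an estimated correlation). MHC class I genes were higher (15 of 17 under each drug, medians 0.29 and 0.38, adjusted p = 0.114 and 0.126 with an estimated correlation), and so were all 13 mitochondrially encoded genes (medians 0.43 and 0.46, adjusted p = 0.282 and 0.275 with an estimated correlation). The AP-1 family was lower (10 of 14 under each drug, medians -0.44 and -0.41, adjusted p = 0.0739 and 0.098 with an estimated correlation), with FOS at -2.70 ± 0.049 and JUN at -2.12 ± 0.029 in trametinib. In vemurafenib MHC class II genes (12 of 14 lower, median -0.45, adjusted p = 0.177 with an estimated correlation) and MYC targets (23 of 40 lower, median -0.12, adjusted p = 0.486 with an estimated correlation) were lower. The MHC class II medians were -0.16 with guide 1 and -0.73 with guide 2, and 10 genes were lower with each. Extracellular matrix genes were called lower in vemurafenib (23 of 39, median -0.34, adjusted p = 0.486 with an estimated correlation), although their mean was 0.07 because the collagenase MMP1 (4.58 ± 0.14) and MMP3 (4.39 ± 0.19) rose. P53 targets, oxidative phosphorylation, heat shock and histones were called higher in vemurafenib (medians 0.09, 0.08, 0.04 and 0.41, adjusted p = 0.126, 0.673, 0.486 and 0.486 with an estimated correlation).

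S phase genes did not pass in the knockout under trametinib (15 higher and 10 lower of 36, median 0.04, adjusted p = 0.807) or vemurafenib (15 and 11, median 0.07, adjusted p = 0.558). Nor did G2/M genes (medians -0.05 and 0.06, adjusted p = 0.856 and 0.563). MAPK output (medians -0.38 and -0.07, adjusted p = 0.21 and 0.94) and melanocyte differentiation (medians -0.13 and -0.14, adjusted p = 0.195 and 0.13) did not pass under either drug. The same was true of undifferentiated melanoma (medians 0.08 and 0.05, adjusted p = 0.981 and 0.94) and SAGA (medians 0.03 and 0.03, adjusted p = 0.981 and 0.781). The mean log2-CPM of undifferentiated melanoma was 4.93 in control cells and 5.37 and 5.36 with the guides in trametinib. In vemurafenib it was 5.2 in control cells and 5.59 and 5.6 with the guides. The knockout called 14074 genes in trametinib (6817 higher, 7257 lower, and at least 2-fold 2122 higher and 1199 lower of 3321) and 14004 in vemurafenib (6870 higher, 7134 lower, and at least 2-fold 2134 higher and 1210 lower of 3344). In turn, 10800 and 10905 genes were called with each guide in the same direction, 2363 and 2301 of them at least 2-fold. The guides' effects had r = 0.909 in trametinib and 0.907 in vemurafenib, with covariances of 0.756 and 0.779 against simulated ones of 0.028 and 0.0269 and a simulated r of 0.498 and 0.496. Adjusted over the list alone, S phase had 16 higher in trametinib and 18 in vemurafenib, G2/M had 11 lower in vemurafenib, and the melanocyte list had 12 and 13 lower. Signs of median, mean and test differed for 9 lists in trametinib and 10 in vemurafenib, undifferentiated melanoma and SAGA among them, and of these only extracellular matrix in vemurafenib was called.

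In knockout cells given trametinib DCT rose 376-fold and the surface protein CD24 47.3-fold, MAP1LC3C 49.9-fold, the selenium transporter SELENOP 24.6-fold and the cell death gene BMF 23.6-fold, while CXCL8 fell 295-fold, DUSP6 228-fold, SPRY4 163-fold, ETV4 91.4-fold, ETV5 89.5-fold and CEMIP 85.8-fold. C4A rose 24.7-fold with trametinib and 21.6-fold with vemurafenib, and C4B 19.4-fold with vemurafenib, but these near-identical copies share reads. With vemurafenib DCT rose 361-fold, MAP1LC3C 18.2-fold, CD24 17.3-fold and COL21A1 15.9-fold, and CEMIP fell 83-fold, CXCL8 71.1-fold, SPRY4 39.6-fold, DUSP6 19.8-fold, SERPIND1 38.2-fold, TMEM158 33.2-fold and ETV4 32.1-fold. MAPK output fell with each drug (24 and 25 of 25 lower, medians -3.02 and -2.50), as did G2/M (30 of 30 lower, medians -2.45 and -2.26). Also lower were S phase (36 of 36 lower, medians -1.62 and -1.63), MYC targets (40 of 40 lower, medians -0.96 and -0.88), and inflammatory cytokines and NF-kB (20 of 24 lower, medians -1.41 and -1.48). CCND1 fell 8.1-fold and 5.92-fold, EGFR 3.28-fold and 2.75-fold, AXL 1.22-fold and 1.33-fold and NGFR 1.14-fold and 1.69-fold with trametinib and vemurafenib. The first NGFR value is a mean over the guides, whose levels went from 49.4 CPM ± 2.03 to 52.6 ± 1.4 with guide 1 and from 35.9 ± 1.68 to 26.1 ± 1.95 with guide 2. MITF rose 1.58-fold and 1.63-fold and SOX10 1.07-fold and 1.11-fold. MLANA did not pass with trametinib (log2 0.24 ± 0.11, adjusted p = 0.056) or vemurafenib (log2 0.04 ± 0.12, adjusted p = 0.78), and without replicate 1 of guide 1 in DMSO the first passed (log2 0.28). Camera called 17 lists for trametinib and 20 for vemurafenib, of which 10 and 10 held with an estimated correlation. Heat shock, cholesterol synthesis and YAP/TEAD targets fell (medians -0.89, -0.47 and -0.33 with trametinib, -0.86, -0.45 and -0.34 with vemurafenib) and p53 targets rose (medians 0.28 and 0.27), and all held. Undifferentiated melanoma fell with trametinib (20 of 28 lower, median -0.83) but had adjusted p = 0.137 with an estimated correlation for vemurafenib (median -0.46). Glycolysis and the ATF4 list were lower with trametinib (medians -0.41 and -0.39, adjusted p = 0.175 and 0.228 with an estimated correlation) and vemurafenib (medians -0.47 and -0.37, adjusted p = 0.137 and 0.184 with an estimated correlation). Interferon response, MHC class I, MHC class II and lysosome genes were higher with trametinib (medians 0.32, 0.36, 0.30 and 0.21, adjusted p = 0.438, 0.257, 0.228 and 0.321 with an estimated correlation) and vemurafenib (medians 0.32, 0.39, 0.52 and 0.26, adjusted p = 0.378, 0.226, 0.0667 and 0.296 with an estimated correlation). TGF-beta targets were lower with trametinib (median -0.31, adjusted p = 0.228 with an estimated correlation). With vemurafenib hypoxia response was lower (median -0.42, adjusted p = 0.137 with an estimated correlation), and neural crest-like and mitochondrially encoded genes were higher (medians 0.27 and 0.17, adjusted p = 0.226 and 0.631 with an estimated correlation). Melanocyte differentiation rose with vemurafenib (14 of 23, median 0.50, adjusted p = 0.0134). Signs of median, mean and test differed for 2 uncalled lists with trametinib and 4 with vemurafenib, the BCL2 family and histones among them. Trametinib called 18003 genes (9366 higher, 8637 lower, and at least 2-fold 3335 higher and 2173 lower of 5508) and vemurafenib 17422 (9077 higher, 8345 lower, and at least 2-fold 2934 higher and 1869 lower of 4803). With trametinib, melanocyte differentiation (13 higher and 7 lower of 23, median 0.42, adjusted p = 0.0705) did not pass, and adjusted over the list alone 14 of its genes were higher.

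The interaction asks whether a drug's effect differed between knockout and control cells. JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327, minus strand), an AP-1 subunit, rose with trametinib from 9.5 CPM ± 0.636 to 611 ± 22.4 in control cells. In knockout cells it rose from 13.3 ± 0.586 to 208 ± 3.05 with guide 1 and from 16.5 ± 1.19 to 94.7 ± 2.16 with guide 2, a difference in response of log2 -2.76 ± 0.053. CCN3 (ENSG00000136999, chromosome 8, 119416306 to 119424353, plus strand) rose from 7.83 CPM ± 0.308 to 496 ± 7.21 in control cells and from 36.8 ± 0.79 to 254 ± 8.95 and from 35.2 ± 1.09 to 79.3 ± 0.898 with the guides (log2 -4.01 ± 0.045). GRIN2A (-4.41 ± 0.24), the transporter SLC6A12 (-4.24 ± 0.22), RSAD2 (-3.84 ± 0.57), NAV3 (-3.77 ± 0.15) and NAV2 (-3.50 ± 0.072) also responded less in knockout cells. The glycolipid enzyme A4GALT (4.11 ± 0.22), the receptor ADGRF1 (3.78 ± 0.25), PDZD2 (3.68 ± 0.092), ANO4 (3.17 ± 0.19), LOXL4 (3.11 ± 0.041) and the cell cycle factor E2F2 (2.97 ± 0.18) had the largest positive differences. E2F2 fell with trametinib from 18.1 CPM ± 0.596 to 0.364 ± 0.12 in control cells and from 10.9 ± 0.409 to 1.49 ± 0.267 with guide 1. For vemurafenib the largest differences were those of ADGRF1 (3.30 ± 0.22), A4GALT (3.20 ± 0.18), LPL (2.89 ± 0.15), LOXL4 (2.75 ± 0.04), ANKRD1 (2.69 ± 0.12) and PDZD2 (2.65 ± 0.082) upward. Downward they were those of SLC6A12 (-3.81 ± 0.23), NAV2 (-3.53 ± 0.073), PKIB (-3.50 ± 0.17), NAV3 (-3.49 ± 0.16), CCN3 (-3.47 ± 0.045) and RAB3B (-3.39 ± 0.078). The response of CCND1 differed by 0.87 ± 0.041 with trametinib and 1.18 ± 0.041 with vemurafenib, and of SPRY4 by 0.72 ± 0.095 and 1.38 ± 0.062. That of DUSP6 differed by -0.71 ± 0.13 and -0.90 ± 0.058, of NGFR by -0.92 ± 0.053 and -0.86 ± 0.054, and of MLANA by -1.06 ± 0.21 and -1.15 ± 0.21. EGFR (0.61 and 0.33), AXL (0.35 and 0.39), TADA2B (-0.29 and -0.44), MITF (-0.17 and -0.21) and SOX10 (-0.15 and -0.17) were called too.

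Cell cycle genes fell less with either drug in knockout cells than in control cells. For trametinib the difference was positive for 32 of 36 S phase genes (median 0.68, adjusted p = 2.13e-17, MCM10 1.81 ± 0.14) and 30 of 30 G2/M genes (median 0.47, adjusted p = 1.53e-15, BUB1B 0.91 ± 0.058). For vemurafenib it was positive for 33 of 36 (median 0.69) and 29 of 30 (median 0.56). MYC targets (34 and 31 of 40 positive, medians 0.33 and 0.29, NME1 0.96 ± 0.054 with trametinib) followed. Heat shock (14 and 15 of 19 positive, medians 0.28 and 0.33) held with an estimated correlation for vemurafenib alone, with adjusted p = 0.0786 with an estimated correlation for trametinib. The AP-1 family had negative differences (9 and 10 of 14, medians -0.77 and -0.68, adjusted p = 4.8e-06 and 4.02e-06), with ATF3 at -2.96 ± 0.081 and FOS at -2.60 ± 0.082 for trametinib. Inflammatory cytokines and NF-kB (13 of 24 negative for each drug, medians -0.34 and -0.29, PTGS2 -2.64 ± 0.19) and p53 targets (12 and 13 of 24 negative, medians -0.15 and -0.18, CDKN1A -0.74 ± 0.041, but PMAIP1 2.26 ± 0.13) were negative as well. Neural crest-like genes (17 of 22 negative for each, medians -0.53 and -0.56, GAP43 -2.10 ± 0.19) and melanocyte differentiation (11 of 23 negative for each, medians -0.33 and -0.31) had negative differences, as had TGF-beta targets (15 of 24 negative for each, medians -0.50 and -0.54, PMEPA1 -2.93 ± 0.04). These 3 lists held with an estimated correlation for vemurafenib, and for trametinib had, in that order, adjusted p = 0.0574, 0.0592 and 0.071 with an estimated correlation. MAPK output did not pass for trametinib (11 positive and 9 negative of 25, median 0.08, adjusted p = 0.627) or vemurafenib (11 and 8, median 0.19, adjusted p = 0.209). Nor did undifferentiated melanoma (medians 0.36 and 0.21, adjusted p = 0.396 and 0.593) or SAGA (medians -0.12 and -0.16, adjusted p = 0.188 and 0.0877).

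Called with the preset correlation alone for both interactions were interferon response (28 of 42 negative for each, medians -0.47 and -0.45, adjusted p = 0.208 and 0.21 with an estimated correlation) and lysosome (28 and 30 of 40 negative, medians -0.23 and -0.26, SQSTM1 -1.10 ± 0.04, adjusted p = 0.126 and 0.0961 with an estimated correlation). So were the BCL2 family of cell death regulators (10 and 11 of 16 negative, medians -0.25 and -0.27, HRK -1.77 ± 0.12, adjusted p = 0.0786 and 0.0549 with an estimated correlation) and histones (11 and 12 of 36 negative, adjusted p = 0.376 and 0.471 with an estimated correlation). The histone calls use the same low replicate of control cells in DMSO and cover only transcripts with a polyA tail. Glycolysis (17 and 18 of 22 positive, medians 0.40 and 0.31, LDHA 0.73 ± 0.032, adjusted p = 0.0868 and 0.0744 with an estimated correlation) had positive differences. So had oxidative phosphorylation (19 and 25 of 35 positive, medians 0.19 and 0.23, adjusted p = 0.298 and 0.187 with an estimated correlation) and cholesterol synthesis (14 and 12 of 24 positive, medians 0.26 and 0.20, adjusted p = 0.0987 and 0.0549 with an estimated correlation). YAP/TEAD targets were called for trametinib (12 of 26 positive, median 0.10, adjusted p = 0.163 with an estimated correlation). The interaction called 11066 genes for trametinib (5231 positive, 5835 negative, and at least 2-fold 989 and 1274 of 2263) and 10699 for vemurafenib (5044 positive, 5655 negative, and at least 2-fold 834 and 1140 of 1974). Adjusted over the list alone, the interaction with trametinib had 35 positive MYC targets, 15 heat shock and 23 oxidative phosphorylation genes, and 12 negative melanocyte and 10 negative AP-1 genes. Signs of median, mean and test differed for 6 uncalled lists with trametinib and 3 with vemurafenib.

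**Figure D4:**
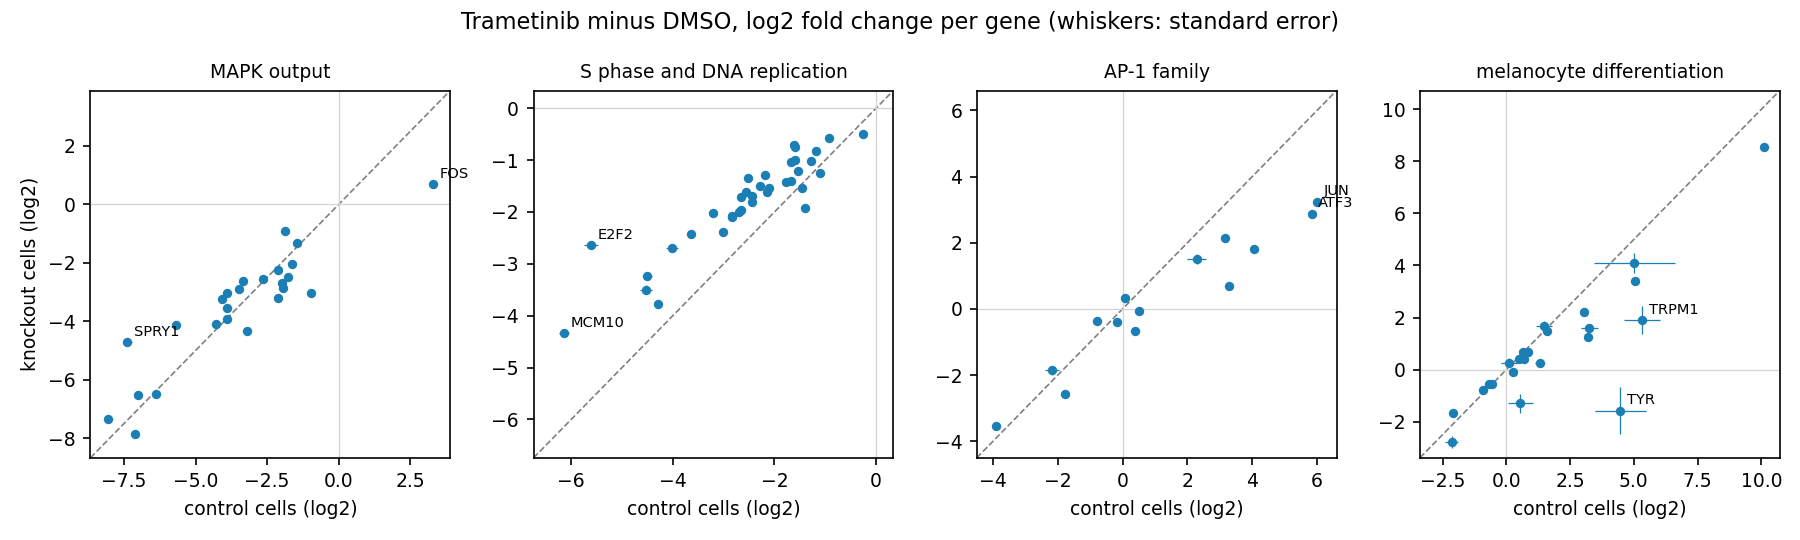
Log2 fold change of trametinib against DMSO per gene in control cells (horizontal) and TADA2B knockout cells (vertical, mean of both guides) for 4 gene lists, with standard errors as whiskers and equal responses on the dashed line. S phase genes lie above the line for 32 of 36 genes called different, while MAPK output genes lie on either side of it (11 higher and 9 lower of 25 called).

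The guides were compared with each other to see how far the knockout populations differ. In DMSO 3008 genes were called, 1170 higher and 1838 lower with guide 2, of which 209 differed at least 2-fold (81 higher, 128 lower). In trametinib 4954 genes were called (2710 higher, 2244 lower, and at least 2-fold 56 higher and 233 lower of 289), and in vemurafenib 4026 (1795 higher, 2231 lower, and at least 2-fold 75 higher and 215 lower of 290). JUN in trametinib stood at 94.7 CPM ± 2.16 with guide 2 and 208 ± 3.05 with guide 1, and SPRY4 in DMSO at 119 CPM ± 2.71 and 194 ± 2.66. EGFR, SOX10 and NGFR each lay farther from control with guide 2 than with guide 1 in DMSO, at 70.7 against 49.8 CPM, 274 against 459 CPM and 35.9 against 49.4 CPM. DUSP6 and AXL went the other way and lay farther from control with guide 1.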

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

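The tests of the explanations weighed here, and the counts of other splits of the libraries, were chosen only after the results were seen, while the tests of the interaction and of the guides against each other were planned. What marked the results listed first is a tested difference between groups, either in the response of knockout and control cells to a drug or between the guides. The rises of keratinocyte markers and interferon response genes in DMSO are differences between knockout and control cells. They were taken up for weighing after the results were seen.

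The response differed between knockout and control cells for 11066 genes with trametinib and 10699 with vemurafenib, and guide 1 and guide 2 differed for 3008 genes in DMSO, 4954 in trametinib and 4026 in vemurafenib (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). With trametinib the log2 difference in response was 4.11 for A4GALT, 3.78 for ADGRF1, 3.68 for PDZD2, 3.17 for ANO4, 3.11 for LOXL4 and 2.97 for E2F2. It was -4.41 for GRIN2A, -4.24 for SLC6A12, -4.01 for CCN3, -3.84 for RSAD2, -3.77 for NAV3 and -3.50 for NAV2. With vemurafenib it was 3.30 for ADGRF1, 3.20 for A4GALT, 2.89 for LPL, 2.75 for LOXL4, 2.69 for ANKRD1 and 2.65 for PDZD2. It was -3.81 for SLC6A12, -3.53 for NAV2, -3.50 for PKIB, -3.49 for NAV3, -3.47 for CCN3 and -3.39 for RAB3B. For trametinib and vemurafenib in turn, it was -0.29 and -0.44 for TADA2B, -0.71 and -0.90 for DUSP6, 0.72 and 1.38 for SPRY4, and 0.87 and 1.18 for CCND1. It was -0.17 and -0.21 for MITF, -1.06 and -1.15 for MLANA, and -0.15 and -0.17 for SOX10. It was -0.92 and -0.86 for NGFR, 0.35 and 0.39 for AXL, and 0.61 and 0.33 for EGFR.

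Lists with a positive median difference in response (knockout minus control), for trametinib and vemurafenib in turn, were S phase (0.68 and 0.69), G2/M (0.47 and 0.56), glycolysis (0.40 and 0.31), MYC targets (0.33 and 0.29), heat shock (0.28 and 0.33), cholesterol synthesis (0.26 and 0.20) and oxidative phosphorylation (0.19 and 0.23), and YAP/TEAD targets for trametinib alone (0.10). These lists fell with the drugs in control cells, so a positive value is a smaller fall in knockout cells. Of the lists called with the preset correlation, 12 of 18 for trametinib and 7 of 17 for vemurafenib were lost with an estimated correlation. These were glycolysis, cholesterol synthesis, oxidative phosphorylation, interferon response, lysosome, the BCL2 family and histones for both drugs, and melanocyte differentiation, neural crest-like genes, YAP/TEAD targets, TGF-beta targets and heat shock for trametinib alone. Negative medians were those of the AP-1 family (-0.77 and -0.68), neural crest-like genes (-0.53 and -0.56), TGF-beta targets (-0.50 and -0.54), interferon response (-0.47 and -0.45), NF-kB (-0.34 and -0.29), melanocyte differentiation (-0.33 and -0.31), the BCL2 family (-0.25 and -0.27), lysosome (-0.23 and -0.26), histones (-0.21 and -0.26) and p53 targets (-0.15 and -0.18). A negative value can be a smaller rise or a larger fall, and NF-kB genes fell more by median in knockout cells.

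Cell cycle genes fell less with the drugs in knockout cells, the S phase list at 71.3% (SE 1.3) of the response in control cells with trametinib and 68.9% (SE 1.6) with vemurafenib, and the G2/M list at 83.2% (SE 2.5) and 79.7% (SE 2.1). Here and in the next paragraphs, an SE pools the 6 knockout libraries of both guides as 1 group beside the 3 control libraries. It does not treat the guides as separate populations. The mean response of MAPK output to trametinib was 101% (SE 2) of control, but its members went both ways. By the difference in response, CCND1 (0.87) and SPRY4 (0.72) fell less in knockout cells and DUSP6 (-0.71) fell more. With each guide, SPRY4 lay below control in DMSO and also under each drug, so its smaller fall is no sign of weaker action. CCND1 lay below control in DMSO and above it under each drug. The mean argues against a weaker action on the list as a whole and leaves single genes such as CCND1 open. With vemurafenib the mean response of MAPK output was 92.7% (SE 2.5), again over members that went both ways. CCND1 (1.18) and SPRY4 (1.38) fell less in knockout cells and DUSP6 (-0.9) fell more. This mean argues against a weaker action on the list as the whole cause, and leaves open a part in it and in single genes. In S phase genes the mean log2-CPM of knockout cells lay 0.64 below control in DMSO (SE 0.011). It differed by 0.08 (SE 0.033) in trametinib and 0.13 (SE 0.038) in vemurafenib. By guide, the mean was 3.67 and 3.79 against 3.64 in control cells in trametinib, and 3.74 and 3.9 against 3.69 in vemurafenib. These levels make up the difference in response itself, so they restate the smaller fall and cannot test its cause. That a lower level before the drug accounts for the smaller fall stays a hypothesis.

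Keratinocyte markers were higher in knockout cells in DMSO. The summed level of KRT5, KRT14, KRT6A, KRT16 and KRT17, abundant in keratinocytes, differed by -1.41 CPM (SE 1.3, 9.55 in control and 8.15 in knockout cells) while LAMB3 rose by 59.6 CPM (SE 5.2), which argues against keratinocytes mixed into the cultures. The 11 markers that are not keratins had a median of 0.95, with 10 called higher, which argues against reads shared between keratin genes. With each guide 14 members were called higher, and an effect of TADA2B loss and the history of the knockout populations cannot be told apart, because each control library comes from 1 population that has another history.

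Interferon response genes were higher in knockout cells in DMSO (median 1.11) and had a median of 0.73 in trametinib (adjusted p = 0.114 with an estimated correlation), where S phase genes no longer lay below control, which argues against a slower cell cycle as the whole cause. The median difference in response was -0.47 (adjusted p = 0.208 with an estimated correlation), so a part of the cell cycle in it stays open. PTPRC, CD53 and TYROBP, transcripts of leukocytes, differed in sum by 0.0442 CPM (SE 0.031) while IFI6 rose by 53.6 CPM (SE 2), which argues against leukocytes in the cultures as the source of that rise. Of 14 leukocyte markers 8 were called higher and 2 lower (median 0.93), from a mean log2-CPM of -1.13 in control cells to -0.35 with guide 1 and -0.24 with guide 2, but the list did not pass (adjusted p = 0.0672), and the source of these low levels is open. With each guide 39 interferon response genes were called higher, and the history of the populations, such as a response to their making, cannot be told apart from TADA2B loss for the same reason.

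Other splits of the libraries were counted with fits of the libraries compared alone, so the real counts differ from those above. In each case 1 split, the real one, gave as many genes. For the knockout, 100 of 840 possible splits were drawn, for the drugs in knockout cells 100 of 200 and for the interactions 100 of 705600. Of 100 splits, the real one called 17816 genes for trametinib in knockout cells (highest other 8066), 16939 for vemurafenib in knockout cells (5910), 14457 for the knockout in DMSO (11085), 13929 in trametinib (11175) and 13384 in vemurafenib (10367). It called 11250 for the interaction with trametinib (9914) and 10644 with vemurafenib (3133). With each guide it called 11656, 10855 and 10503 in DMSO, trametinib and vemurafenib (2770, 3951 and 3028). The median count over the other drawn splits was 0 in each case. Splits for the knockout could also trade libraries between the guides alone, which leaves knockout and control libraries apart. For these 10 results no other drawn split gave as many genes, but many splits were not drawn. Libraries within a group were much alike, so the real split was likely to rank first whatever set the groups apart. With 1 control population, chance in how the populations were made is not tested. The splits do not tell TADA2B loss from other differences between the populations. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real counts were 16424 for trametinib and 16124 for vemurafenib in control cells, 4027 between the drugs, and 4163, 5292 and 3283 between the guides in DMSO, trametinib and vemurafenib, with 0 genes in the highest other split by edgeR.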

How the results depend on the processing

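No test here was chosen after the results were seen. Counts of called genes stayed within 1.5 times under RLE size factors, no low-count filter, at least 1 CPM in 3 libraries, DESeq2, limma voom, only the groups compared, a replicate block and leave-one-out, and no named gene or list reversed. The balance of higher and lower calls was less stable. Under RLE it turned for the knockout in DMSO (7252 higher, 7369 lower), trametinib (7057, 6974) and vemurafenib (7070, 6918), for both guides in trametinib (5501, 5224) and for the interactions (5579, 5513 and 5352, 5348), and DESeq2 turned the same counts. With only the groups compared it turned for the knockout in trametinib (7017, 6912) and vemurafenib (6851, 6533), both guides in trametinib (5624, 5231), the guides against each other in trametinib (2633, 2659) and between the drugs (1961, 2066). At 1 CPM and with voom it turned for the knockout in DMSO (6384, 6435 and 7118, 7290) and both guides in vemurafenib (4871, 5192 and 5374, 5533). Single libraries turned it between the drugs (control_vemurafenib replicate 1: 1753, 1757), between the guides in trametinib (TADA2B_guide1_trametinib replicate 1: 2054, 2152), for both guides in trametinib (the same library: 5189, 5133; control_trametinib replicate 3: 5119, 5072) and in vemurafenib (control_vemurafenib replicate 2: 5105, 5142). At least 2-fold turned it for the knockout in trametinib (2122, 1199) and vemurafenib (2134, 1210), both guides in trametinib (1683, 680) and the guides in trametinib (56, 233). The cause of these turns was not tested. Requiring at least 2-fold left 7454 genes for trametinib and 6920 for vemurafenib in control cells, 362 between the drugs, 5508 and 4803 for the drugs in knockout cells, 3178, 3321 and 3344 for the knockout in DMSO, trametinib and vemurafenib, 2268, 2363 and 2301 with each guide, 2263 and 1974 for the interactions, and 209, 289 and 290 between the guides, by the construction of that setting. TADA2B with guide 2 in DMSO ranged from -0.147 to -0.089 with single libraries left out, and 2 of these fits ended the call. Of 900 gene results, DESeq2 left 897 on their side of the threshold, RLE 897, voom 893 and the block 900. With single libraries left out, counting each gene's lowest and highest value, 1764 stayed on their side of the threshold, called or not, 30 lost a call in some fit and 6 gained one. Of 330 list results, 80 lost their call with an estimated correlation and 127 gained one with fry. The replicate numbers share no more than a number. Of 27 libraries 11 correlated best with their own number, 108 pairs of equal number had r from -0.512 to 0.455, and the block gave 17332 genes for trametinib and 16906 for vemurafenib in control cells and 14528 for the knockout in DMSO. Depth limits genes near the floor of 3 counts, 0.0444 CPM in the shallowest library.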

Other observations

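The tests of the hypothesis below were chosen only after the results were seen.

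The knockout in DMSO and the drugs in control cells moved many genes the same way. Of the genes called in both, 8800 had the same sign for the knockout and trametinib (4373 higher, 4427 lower) and 3021 opposite signs, and for vemurafenib 8589 and 3011. Independent lists of these sizes would share 2690 higher and 2345 lower genes for trametinib and 2634 and 2280 for vemurafenib. Simulations of unchanged groups that share the controls gave 0 shared genes. With no gene changed, few calls can arise, so this count does not show what shared controls add. S phase and MYC target genes fell and p53 targets rose in each, while MAPK output fell with the drugs and did not pass in the knockout. Other lists went opposite ways: NF-kB rose in the knockout (median 0.78) and fell with trametinib and vemurafenib (-0.74 and -1.29), and neural crest-like genes fell in the knockout (-0.38) and had higher medians with the drugs (0.66 and 0.69). A hypothesis is that TADA2B loss alone gives part of the state that the drugs give. The covariance across genes was 0.454 with trametinib and 0.413 with vemurafenib, against highest simulated values of 0.0292 and 0.0293 for unchanged groups that share the control libraries. The Pearson r was 0.338 and 0.33, below the simulated medians of 0.587 and 0.586. The simulated r in unchanged groups comes from the shared noise alone, so the covariance is compared instead. The covariance exceeds what shared controls gave, but slower division in both could give the same, and the opposite lists limit the hypothesis to part of the genes.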
